A study of Homo sapiens with 8 samples.

How the data were processed

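Messenger RNA levels were measured by RNA sequencing of peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes left when granulocytes and red cells are removed from blood. Per the labels' protocols, the cells came from people given a single 240 mg dose of CD24Fc in a phase I trial, total RNA was extracted with Trizol, RNA of sufficient integrity was used, and libraries followed standard Illumina protocols. The labels give 4 libraries before the dose (Day -1) and 4 libraries after it (Day 3), as 4 pairs of libraries, each pair from 1 person. There is no group without the drug, so a change between the days cannot be separated from a change that would have occurred without it. The library descriptions give a flow cell and lane, which are taken here as the sequencing run. All 4 libraries before and the libraries after of pairs 1 and 4 were on 1 run, and the libraries after of pairs 2 and 3 were on another, so run and day are partly confounded.

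The deposited values are FPKM (fragments scaled by gene length and library depth) per gene and library, made by the authors. Per the submitters' processing notes the tools were FastQC 0.11.5, Trimmomatic 0.35, HISAT2, HTSeq 0.6.1 and DESeq2 with build GRCh38, without their order, settings or annotation. The library preparation's strand setting is not given in the sources used here. The deposited FPKM had been scaled between libraries by the authors: the median ratio of each library to the geometric mean over genes above 0 everywhere was 1.006725 in all 8 libraries. Values of a gene stood in ratios of whole numbers, and whole reads were recovered for 25254 of 25254 genes (tolerance 0.01 reads), which gave 15913797 to 16454855 reads per library. The gene length implied by the deposited FPKM equalled the summed length of every annotated exon line of every transcript for 91.9% of the genes matched to GENCODE release 29, within 1%, and the length of the merged exons for 30.1%. The implied length was 1.59 times the merged exon length at the median, so FPKM of genes with many annotated transcripts are understated relative to other genes. The ratio of 1 gene between libraries is not affected, but an understated FPKM lowers its change on the log2(FPKM + 1) scale and can put it below the filter.

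The table held 25291 genes. Genes of the Y chromosome and of X inactivation (37 genes) were left out of every step, leaving 25254. Gene symbols were matched to GENCODE release 29 on GRCh38 for identifiers and coordinates, and 24585 symbols (97.4%) matched 1 gene. Genes with a mean of at least 1 FPKM over the 8 libraries were tested (12521 genes). Values were transformed to log2(FPKM + 1), so the fold changes are on that scale and understate the change of genes with low values. The test was limma 3.58.1 in R 4.3.3 with the person as a block (model: pair plus day), a mean-variance trend and two-sided Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The fit had 3 residual degrees of freedom and 2.26 prior degrees of freedom. Pairing came from the labels, and in all 4 pairs the 2 libraries deviated from their group means together across genes (correlation across genes from 0.25 to 0.48, each above 0.1).

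In all, 33 gene lists were fixed before the data were examined: blood cell type markers, pathways related to CD24 and inflammation, and signs of handling, metabolism and RNA quality. Lists with at least 5 genes tested (31 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 31 lists. Beside it stand camera with a correlation estimated for each list and fry, which tests whether a list's genes move one way on balance without comparing them with other genes. The rule for named genes was also fixed beforehand. Per direction it takes up to 12 genes by smallest p, first those past the adjusted threshold, then those with 1 sign in all 4 pairs and a log2 change of at least 0.3 in size. It adds up to 4 members per list by smallest p and 14 fixed genes. Genes of germline copy number or HLA haplotype, immunoglobulin and T cell receptor segments, KIR genes, pseudogenes and clone names were left out of it.

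The fit was tested on simulated data with the real genes' means and spread: for day 3 against day -1 over 12521 genes, 26% of 50 genes changed by 0.5 on the log2 scale, 96% of 50 changed by 1, 94% of 50 changed by 2 and 100% of 50 changed by 4 were recovered. Of 12023 unchanged genes 7 were called. Camera with the preset correlation called 20 of 20 simulated lists shifted by 0.3 and 0 of 100 unshifted lists, and with an estimated correlation it called 0 of the 20. The simulation drew genes independently, which real genes of 1 cell type are not. The estimated correlation was, for example, 0.91 for the platelet list and 0.48 for the NK and cytotoxic list. The 0 of 100 therefore does not show how often the preset correlation calls correlated lists that are not shifted. The changed genes and shifted lists were simulated together, which eases the adjusted threshold for each gene. The shares recovered may therefore overstate what the fit finds where few genes change. In the real data CXCL5, with a log2 change of -1.15 (SE 0.17), did not pass (adjusted p 0.70 in limma).

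Alternatives covered the block, the pseudocount, the filter, 4 rescalings, the variance model, the sequencing run as a term, the pairs on 1 run alone and leaving out each pair. Rescaling to equal sums (TPM) set every library's FPKM sum to the geometric mean of the sums, so the gene set and the pseudocount kept their meaning. A value that changed sign without passing the threshold in either setting was counted as moved, and one that changed sign after passing in either as reversed. limma's voom on the recovered reads, the mitochondrial list without MT-ATP8 and an estimated correlation with the run as a term were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and the table was read with pandas 2.3.3, numpy 2.4.6 and Python 3.11.15. With 4 pairs an exact sign-flip test of 1 value cannot give a two-sided p under 0.125, so single values are given with their spread. Results of 3 genes, among them 1 of the 17 checks in which a library stood apart, are not reported here.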

Results

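The study asked how CD24Fc acts on the human immune system. CD24Fc is a fusion of the extracellular part of CD24 with an antibody Fc region, and CD24 is a surface glycoprotein that binds SIGLEC10 and restrains responses to molecules released by damaged cells. Gene expression in PBMC was compared between Day 3 after a single dose of 240 mg and Day -1 before it, in 4 pairs of libraries. Each library held 15913797 to 16454855 recovered reads, and values are FPKM given as mean ± SD with n = 4 libraries per group.

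No single gene passed the test, while gene lists of several blood cell types moved. After the dose platelet, histone, mitochondrially encoded, B cell, MHC class II and classical monocyte lists fell, and the list of NK (natural killer) and cytotoxic cell markers rose. Of 12521 genes tested, 0 were raised and 0 lowered at an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.70. At an unadjusted p under 0.05 there were 726 genes (5.80%), 263 higher and 463 lower, against 626 expected by chance. limma's voom on the recovered reads also called 0 genes, with 715 past the unadjusted threshold. Of the 31 lists tested, camera with the preset correlation moved 15, 6 up and 9 down. None of these calls held with an estimated correlation (lowest adjusted p 0.32) or with fry. Over all 31 lists the lowest adjusted p with fry was 0.16, for neutrophil markers, which camera did not call. Among the 15 called lists the lowest with fry was 0.19.

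Platelet markers, the transcripts of cell fragments that commonly accompany PBMC, showed the greatest list change. The list fell by 0.89 ± 0.57 on the log2 scale (mean ± SD, n = 4 pairs), with 15 of 15 members lower on average and 14 of them lower in all 4 pairs. CAVIN2, a caveola protein abundant in platelets, had 45.0 ± 6.89 FPKM before and 19.96 ± 6.46 after, a log2 change of -1.18 (SE 0.24). TUBB1, the platelet tubulin, had 47.3 ± 10.8 before and 22.1 ± 9.35 after, and PF4, a chemokine stored in platelet granules, 133 ± 63.7 before and 68.2 ± 49.2 after. GP1BA, part of the von Willebrand factor receptor, had 2.94 ± 0.449 before and 2.53 ± 0.560 after and was lower in 3 of the pairs. Adjusted over the list alone 14 of 15 members passed, and adjusted over all genes tested 0 did. The camera adjusted p was 5.85e-18, and the adjusted p = 0.32 with an estimated correlation, which was 0.91 for this list. The change was -0.36 and -1.62 in the pairs on 1 run and -0.53 and -1.07 in the pairs across 2 runs. Genes that led the ranking of lowered genes outside the lists included CXCL5, a chemokine (8.39 ± 3.05 before and 3.24 ± 1.76 after), PRKAR2B, a regulatory subunit of protein kinase A (14.8 ± 1.89 and 7.46 ± 2.47), MAP3K7CL (4.00 ± 0.969 and 1.72 ± 0.661), C2orf88 (3.69 ± 0.460 and 1.75 ± 0.624) and SH3BGRL2 (6.35 ± 1.05 and 3.25 ± 1.26). Each of these 5 was lower in all 4 pairs at an adjusted p of 0.70 in limma. Each also fell less in pairs 1 and 2 than in pairs 3 and 4, as the platelet list did, so they cannot be taken as separate changes. CXCL5, for example, changed by -0.76, -0.84, -1.46 and -1.55 in pairs 1 to 4.

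Replication-dependent histone genes fell by 0.64 ± 0.42 (7 of 7 members lower, 6 in all 4 pairs). Their changes in pairs 1 to 4 were -0.41, -0.23, -0.74 and -1.18, beside -0.36, -0.53, -1.07 and -1.62 for the platelet list, so both were largest in pair 4 and next in pair 3. HIST1H2AC had 16.2 ± 2.76 FPKM before and 8.39 ± 3.81 after, HIST2H2BE 20.5 ± 0.791 and 11.9 ± 4.22, and the linker histone HIST1H1C 13.7 ± 3.41 and 9.57 ± 2.78. Adjusted over the list alone 6 of 7 passed, and adjusted over all genes 0. The camera adjusted p was 1.36e-09, with adjusted p = 0.32 with an estimated correlation.

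The 13 protein-coding genes of the mitochondrial genome fell by 0.51 ± 0.27, with 13 of 13 lower and 12 lower in all 4 pairs. MT-CO1, a cytochrome c oxidase subunit, had 8638 ± 1080.5 FPKM before and 7069 ± 1399 after. MT-ND3, a complex I subunit, had 2399 ± 503 before and 1819.6 ± 475 after. The ribosomal RNAs MT-RNR1 and MT-RNR2, named by their rank, had log2 changes of -1.15 (SE 0.21) and -1.02 (SE 0.17). In pairs 1 to 4 MT-RNR1 changed by -0.66, -0.75, -1.49 and -1.70, and MT-RNR2 by -0.53, -0.90, -1.50 and -1.14. Both fell less in pairs 1 and 2 than in pairs 3 and 4, as the platelet list did, so they cannot be taken as separate from it. The list of 13 protein-coding genes changed by -0.13, -0.70, -0.70 and -0.53. Adjusted over the list alone 11 of 13 passed, and over all genes 0. The camera adjusted p was 1.58e-15, with adjusted p = 0.32 with an estimated correlation. The call was lost under quantile normalization (mean -0.12, adjusted p = 0.63 in limma's camera), and the list mean was -0.33 with the sequencing run as a term. MT-ATP8 differed by run, with 67.0 and 68.8 FPKM in the 2 libraries of the other run against 840 to 1036 in the 6 others, and without it the list mean was -0.39.

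Among lymphocytes, NK and cytotoxic markers rose and B cell markers fell. The NK list rose by 0.29 ± 0.17, with 16 of 16 members higher and 11 higher in all 4 pairs. The list change was 0.43 and 0.29 in pairs 1 and 4, on 1 run, and 0.04 and 0.38 in pairs 2 and 3, across 2 runs. Pair 2 thus showed little rise, and some members counted as higher in all 4 pairs barely changed there (KLRF1 by 0.008). SPON2, a secreted protein expressed by NK cells, had 6.55 ± 0.475 FPKM before and 11.1 ± 2.21 after (log2 change 0.66, SE 0.13). NKG7, a cytotoxic granule protein, had 126 ± 37.4 before and 165 ± 69.2 after, and the receptor KLRF1 11.3 ± 3.39 and 15.9 ± 6.95. GZMB, the granzyme of cytotoxic granules, had 13.9 ± 6.18 before and 14.8 ± 6.83 after and was higher in 2 pairs. Adjusted over the list alone 0 members passed (lowest adjusted p 0.059 in limma), and adjusted over all genes 0. The camera adjusted p was 1.54e-10, with adjusted p = 0.32 with an estimated correlation. Genes outside the list among the 12 named as higher included TXK, a TEC-family kinase (12.9 ± 3.66 before and 17.2 ± 3.36 after), NMUR1, the neuromedin U receptor (8.68 ± 2.25 and 12.9 ± 4.94), KLRC4, a lectin-like receptor gene (6.41 ± 3.70 and 9.11 ± 4.53), and FCRL6, an Fc receptor-like gene. KLRC4 lies beside related receptor genes that can share its reads.

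The B cell list fell by 0.36 ± 0.17, with 13 of 13 members lower and 12 lower in all 4 pairs. CD79B, a signalling chain of the B cell antigen receptor, had 29.1 ± 3.78 FPKM before and 18.7 ± 2.66 after, and MS4A1, which encodes CD20, 26.2 ± 3.80 and 21.4 ± 2.13. BLK was the exception to the pair count, with 10.2 ± 2.75 before and 8.86 ± 2.23 after. Adjusted over the list alone 11 of 13 passed, and over all genes 0. The camera adjusted p was 5.54e-15, with adjusted p = 0.32 with an estimated correlation. T cell markers rose by 0.09 ± 0.09 (11 of 14 higher, camera adjusted p 0.0062), and CD3D, a chain of the T cell receptor complex, had 42.5 ± 4.99 before and 49.4 ± 9.60 after. Genes of T cell activation and checkpoints rose by 0.13 ± 0.05 (11 of 13 higher, camera adjusted p 0.0033), among them PDCD1, which encodes PD-1, with 2.26 ± 1.23 before and 3.14 ± 1.57 after, and TOX with 3.97 ± 1.56 and 5.19 ± 2.17. For both T cell lists the adjusted p = 0.32 with an estimated correlation, 0 members passed when adjusted over the list alone or over all genes, and without the block both calls were lost (adjusted p 0.060 and 0.18 in camera). The change of T cell markers was 0.13 and 0.20 in the pairs on 1 run and 0.03 and 0.01 in the others, and without pair 4 the mean was 0.06 (camera adjusted p 0.11). Without pair 1 the means of T cell markers and of T cell activation and checkpoint genes were 0.08 and 0.11 (camera adjusted p 0.066 and 0.063). The T cell marker call held in 15 of 19 alternatives and that of activation and checkpoint genes in 15 of 18.

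**Figure D1:**
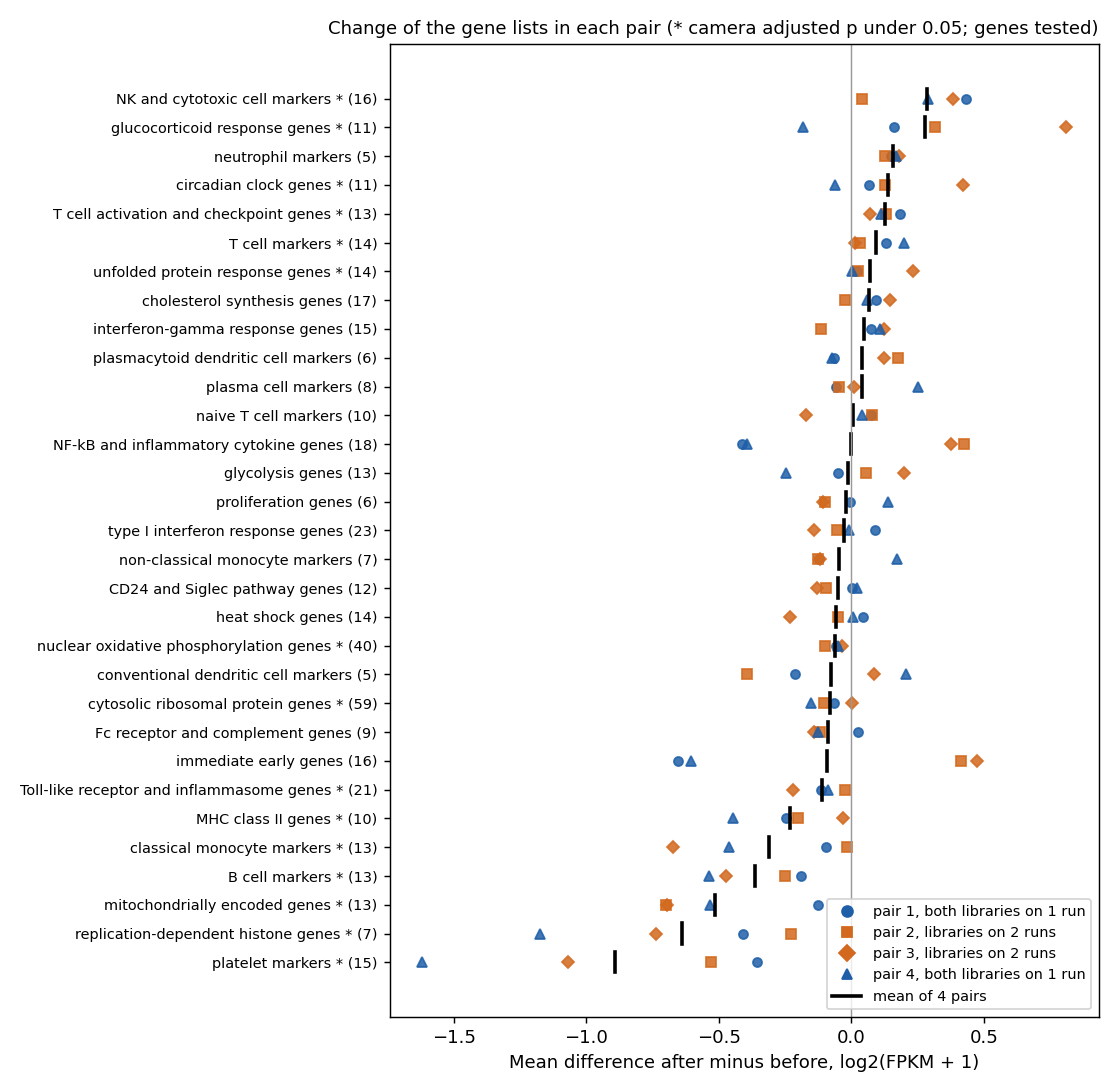
Mean change of each gene list in the 4 pairs, as the difference after minus before in log2(FPKM + 1) on the x axis, for the 31 lists tested on the y axis with the number of genes tested in brackets. Points are pairs, blue where both libraries were on 1 sequencing run and orange where they were on 2, the black bar is the mean of 4 pairs, and stars mark lists called by camera with the preset correlation. Platelet markers lie furthest to the left (mean -0.89), and the blue and orange points lie on opposite sides of 0 for immediate early genes.

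In the myeloid compartment, classical monocyte markers fell by 0.31 ± 0.31, with 13 of 13 lower and 6 lower in all 4 pairs. LYZ, which encodes lysozyme, had 567 ± 96.4 FPKM before and 375 ± 68.2 after. S100A8, a calcium-binding alarmin, had 194 ± 59.1 before and 154 ± 82.6 after, and CD14, the lipopolysaccharide co-receptor, 55.0 ± 8.94 and 51.4 ± 22.7. The camera adjusted p was 3.34e-07, with adjusted p = 0.32 with an estimated correlation, and 0 members passed when adjusted over the list alone. For classical monocyte markers the changes were -0.09 and -0.46 in the pairs on 1 run and -0.02 and -0.67 in the others, and without pair 3 the mean was -0.19 (camera adjusted p 0.00031). MHC class II genes, the antigen presentation genes of B cells and monocytes, fell by 0.23 ± 0.17 (9 of 10 lower). HLA-DRA had 491 ± 73.8 before and 399 ± 61.3 after, and the invariant chain CD74 306 ± 39.3 and 236 ± 39.4. Adjusted over the list alone 5 of 10 passed, and over all genes 0, with a camera adjusted p of 2.27e-08 and adjusted p = 0.32 with an estimated correlation. CD86, a co-stimulatory ligand outside the lists, had 4.10 ± 0.726 before and 3.07 ± 0.662 after and was lower in all 4 pairs. Non-classical monocyte (mean -0.05), conventional dendritic cell (-0.08), plasmacytoid dendritic cell (0.04), neutrophil (0.16), naive T cell (0.01) and plasma cell markers (0.04) did not pass camera's test. For plasma cells the median was -0.05 and the direction of the test was down, opposite to the mean. Of the erythroid list 1 gene and of the immature granulocyte list 0 genes were above the filter, so these 2 lists were not tested.

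**Figure D2:**
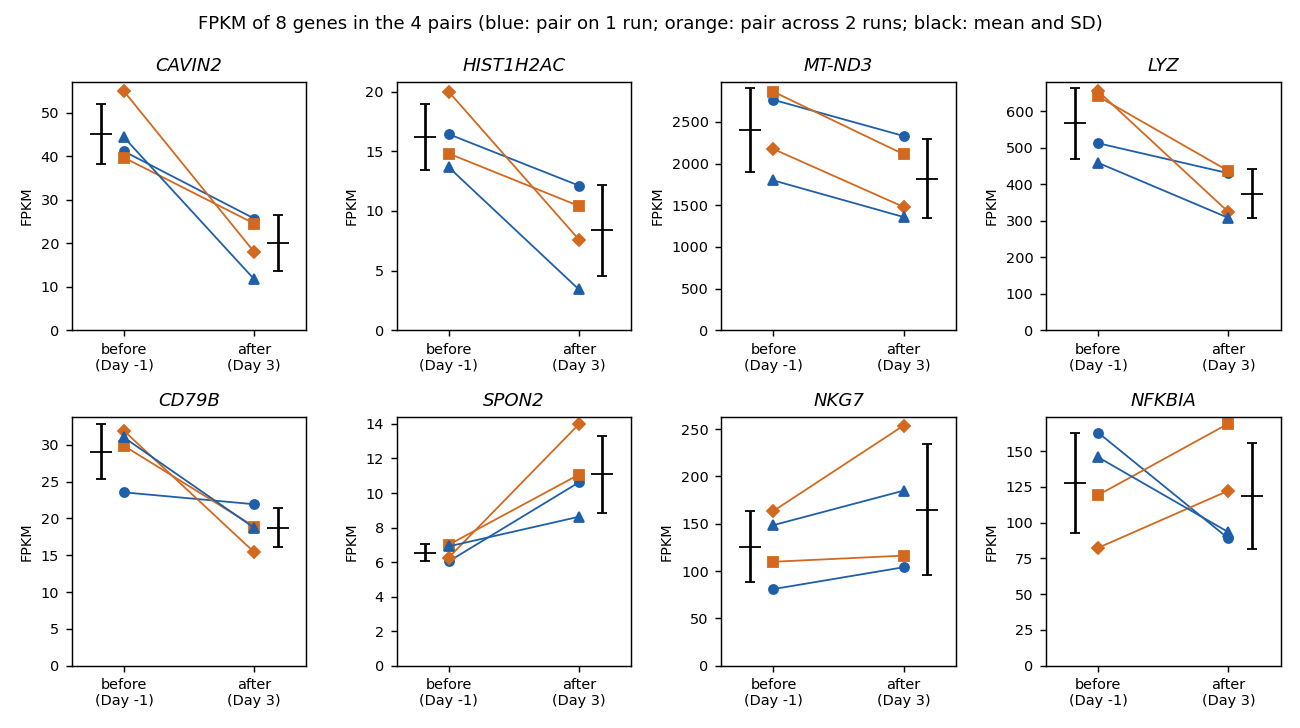
FPKM of 8 genes before (Day -1) and after (Day 3) the dose, with 1 line per pair, blue for pairs on 1 sequencing run and orange for pairs across 2, and the mean and SD of the 4 libraries in black. CAVIN2, HIST1H2AC, MT-ND3, LYZ and CD79B were lower and SPON2 and NKG7 higher in all 4 pairs, while NFKBIA was lower in the blue and higher in the orange pairs. None passed the adjusted test.

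Genes of the CD24 pathway did not pass as a list. The CD24 and Siglec list had a mean change of -0.05 ± 0.07, with a median of 0.00205 against a downward test (camera adjusted p 0.47). CD24 itself had 3.58 ± 0.704 FPKM before and 2.86 ± 1.13 after, lower in 2 of 4 pairs, and its reads can be shared with near-identical pseudogene copies. SIGLEC10, its inhibitory receptor, had 2.27 ± 0.331 before and 2.31 ± 0.220 after. HMGB1, a nuclear protein released by damaged cells, had 18.7 ± 1.03 and 20.2 ± 3.51, and the phosphatase PTPN6 had 20.2 ± 2.07 and 19.4 ± 2.99. SYK, a kinase of immunoreceptor signalling, and CD33, a myeloid Siglec, were lower in all 4 pairs, with log2 changes of -0.24 (SE 0.075) and -0.26 (SE 0.10).

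NF-kB and inflammatory cytokine genes had a mean change of -0.00063 ± 0.46 (camera adjusted p 0.68) and immediate early genes, the fast transcriptional response to cell stimulation, a change of -0.09 ± 0.62 (camera adjusted p 0.10). Behind these means, both lists went in opposite directions in different pairs: immediate early genes changed by -0.65 and -0.60 in the pairs on 1 run and by 0.41 and 0.48 in the pairs across 2 runs, and NF-kB genes by -0.41 and -0.39 against 0.42 and 0.38. With the run as a term, where the change rests on the pairs on 1 run, the means were -0.63 and -0.40 and passed camera with the preset correlation (adjusted p 3.55e-10 and 2.36e-06), with adjusted p = 0.51 with an estimated correlation for both. Without the run term, immediate early genes also passed without pair 2 (mean -0.26, camera adjusted p 0.00015) and without pair 3 (-0.28, 0.00073), and with voom (-0.09, 0.031), and NF-kB genes without pair 2 (-0.14, 0.018). Immediate early genes passed as well after rescaling to equal sums, where their mean was above 0 but below the median of all genes. TNF had 70.2 ± 21.1 FPKM before and 60.1 ± 37.0 after, IL1B 15.9 ± 7.87 and 18.8 ± 7.36, CXCL8 42.5 ± 14.7 and 42.7 ± 10.6, and NFKBIA, the NF-kB inhibitor, 128 ± 35.1 and 119 ± 37.0. IFNG had 3.67 ± 2.58 and 5.52 ± 5.57, and TGFB1 82.8 ± 7.52 and 89.5 ± 23.2. IL6 was below the filter, and IL10 was not analysed here. Toll-like receptor and inflammasome genes fell by 0.11 ± 0.08 (14 of 21 lower, camera adjusted p 0.016), with adjusted p = 0.32 with an estimated correlation. The call held in 12 of 19 alternatives and was lost without pair 1, 3 or 4 (means -0.11, -0.07 and -0.12, camera adjusted p 0.063, 0.070 and 0.075). With the run as a term the mean was -0.10 without passing (adjusted p 0.20 in camera), and after rescaling to equal sums it was 0.000513, the opposite sign. P2RX7, an ATP-gated channel upstream of the inflammasome, was higher in all 4 pairs (log2 change 0.25, SE 0.08), and PYCARD, the inflammasome adaptor, lower in all 4 (-0.25, SE 0.09). Type I interferon (mean -0.03), interferon-gamma (0.05) and Fc receptor and complement genes (-0.09) did not pass. With the run as a term interferon-gamma response genes passed narrowly (mean 0.09, camera adjusted p 0.0496), with adjusted p = 0.68 with an estimated correlation.

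The remaining lists covered hormone, clock, stress and metabolic genes. Glucocorticoid response genes rose by 0.28 ± 0.41 and circadian clock genes by 0.14 ± 0.21 (9 of 11 and 11 of 11 members higher, camera adjusted p 0.012 and 0.0057), with adjusted p = 0.32 with an estimated correlation for both. KLF9, a glucocorticoid-induced factor, had 13.1 ± 3.03 FPKM before and 20.4 ± 8.45 after, and NR1D1, a clock repressor, 6.37 ± 0.895 and 7.66 ± 1.43. Both calls depended on 1 pair: without pair 3 the means were 0.10 and 0.04 (camera adjusted p 0.084 and 0.14), and without pair 4 the glucocorticoid mean was 0.43. In the pairs on 1 run the changes were 0.16 and -0.18 for glucocorticoid response genes and 0.07 and -0.06 for circadian clock genes. With the run as a term, which rests on these pairs, the means were -0.00968 and 0.0022 (camera adjusted p 0.89 and 0.47), so neither rise was seen there. Unfolded protein response genes rose by 0.07 ± 0.11 (11 of 14 higher, camera adjusted p 0.037), with adjusted p = 0.41 with an estimated correlation. This call also depended on pair 3: the pair changes were 0.02, 0.03, 0.23 and 0.00122, and without pair 3 the mean was 0.02 (camera adjusted p 0.53). Without pair 1 or 4 the mean was 0.09 and the call was also lost (camera adjusted p 0.074 and 0.088). With the run as a term it was 0.01 (camera adjusted p 0.52). Nuclear oxidative phosphorylation genes fell by 0.06 ± 0.03 (29 of 40 lower, camera adjusted p 0.0095) and cytosolic ribosomal protein genes by 0.08 ± 0.07 (43 of 59 lower, camera adjusted p 0.00032), with adjusted p = 0.32 and 0.51 with an estimated correlation. After rescaling to equal sums, which moved the median of all genes to 0.11, their means were 0.06 and 0.06. The call of nuclear oxidative phosphorylation genes held in 14 of 19 alternatives. It was lost with the run as a term (mean -0.05, camera adjusted p 0.076) and without pair 1 or 2 (means -0.06 and -0.05, camera adjusted p 0.063 and 0.081). That of cytosolic ribosomal protein genes held in 16 of 19 and was lost, among others, without pair 4 (mean -0.06, camera adjusted p 0.18). The highest camera adjusted p of the ribosomal list over the alternatives was 0.64. In these 5 lists 0 members passed when adjusted over the list alone or over all genes. Cholesterol synthesis genes (mean 0.07), glycolysis genes (-0.01), heat shock genes (-0.06) and proliferation genes (-0.02) did not pass, though cholesterol synthesis genes did without pair 2 (0.10, camera adjusted p 0.015), with no filter (0.07, 0.021) and with voom (0.10, 0.031), and glycolysis genes without pair 3 (-0.08, 0.039). Glycolysis genes also passed with the run as a term (mean -0.15, camera adjusted p 0.016), with adjusted p = 0.65 with an estimated correlation. The nuclear RNAs MALAT1 and NEAT1 had 84.5 ± 8.39 and 27.3 ± 5.94 FPKM before and 76.7 ± 8.91 and 27.6 ± 6.18 after.

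Across all genes, 1625 (12.98%) had 1 direction in all 4 pairs, 769 upward and 856 downward, where independent signs give 1 gene in 8. Over the 8 assignments of day within pairs, 3 gave a share at least as high as the real one, and the highest other share was 26.3%. Changes correlated across genes with r = 0.31 between the 2 pairs across runs and r = 0.16 between the 2 pairs on 1 run, and with r from -0.12 to -0.07 between a pair of one kind and a pair of the other. Genes are not independent replicates, so these r describe only the direction of the shared changes.

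Of the genes named above, these are the places on GRCh38 (GENCODE release 29). SPON2 lies on chromosome 4 from 1166932 to 1208962, TXK on chromosome 4 from 48066393 to 48134256, and NMUR1 on chromosome 2 from 231523160 to 231530495. CXCL5 lies on chromosome 4 from 73995642 to 73998779, CAVIN2 on chromosome 2 from 191834302 to 191847255, and PRKAR2B on chromosome 7 from 107044649 to 107161811. Several small RNA genes also met the naming rule, among them MIR6069, MIR4513, MIR4677, MIR1301, SNORA14 and SNORD11. These 6 rested on means of 0 to 18 reads per group, a depth at which a change cannot be read from 4 libraries. SNORD3A, named as lower by the same rule, rested on means of 60 and 33 reads (log2 change -0.62).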

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

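The test of the run on the 2 inflammatory lists and that of the platelet list with other platelet genes were set before their results were seen, and the other tests here were chosen after the pattern was seen. Within the 4 libraries of a group, 1 library stood apart from the other 3 in 17 of 376 checks of genes, lists and library measures, where chance gives about 19, so single entries carry little weight. The ratio of the gap to the group's range was 0.858 for CXCL5, 0.884 for CD247, 0.915 for FLT3, 0.922 for PROK2, 0.853 for CD24, 0.839 for HSPH1, 0.834 for PKM and 0.834 for MALAT1 before the dose. It was 0.867 for the Fc receptor and complement list and 0.838 for the glucocorticoid list before, and 0.845 for the glucocorticoid list after. After the dose it was 0.927 for NMUR1, 0.931 for SAP30, 0.949 for CD86, 0.978 for P2RX7 and 0.913 for OAS1.

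In 6 of 31 lists the 2 pairs on 1 run went one way and the 2 pairs across runs the other. The difference, pairs across runs less pairs on 1 run, was 1.07 for immediate early genes, 0.80 for NF-kB and inflammatory cytokine genes, 0.27 for glycolysis genes, 0.22 for plasmacytoid dendritic cell markers, -0.17 for heat shock genes and -0.12 for CD24 and Siglec pathway genes. As a run coefficient in limma's camera with the preset correlation, only the immediate early and NF-kB lists passed among the 31 (adjusted p 1.12e-07 and 9.86e-06), with adjusted p = 0.51 with an estimated correlation for both. The other 4 differences had adjusted p of 0.25 to 0.40 in that test. For the same coefficient no gene passed the adjusted threshold in limma, while 1907 genes had an unadjusted p under 0.05. The run term leaves fewer residual degrees of freedom, so these tests cannot show that a run difference is confined to 2 lists.

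The opposite change of immediate early and NF-kB genes is the pattern that most separates the pairs: 10 of 16 and 8 of 18 members were lower in both pairs on 1 run and higher in both others. For the pairs on 1 run a run difference is argued against, since they differed by -0.65 and -0.60 with no difference of run between their libraries. For the pairs across runs it cannot be told apart from the day: the 34 genes' level lay inside the range of the 6 other libraries in 2 of 2 libraries, but that range across people, 0.91 wide, exceeds the change of 0.42 within these pairs, so the bound set beforehand was wrong. The monocyte and immediate early lists had opposite signs in 2 of 4 pairs, the pairs across runs. The monocyte list was lower in all 4 pairs, so this count followed from the pattern itself. In 1 of these 2 pairs the monocyte change was only -0.02. The count therefore cannot decide on a change in the share of monocytes. An offset of the run on top of a fall in all 4 pairs thus stays open, as does a change in the share of monocytes. Handling of the blood between draw and lysis and differences between people were not tested and stay open too.

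The lower platelet list may reflect fewer platelets among the cells taken for RNA. A run difference is argued against by the pairs on 1 run, the smaller of whose changes was -0.36, and library scaling by a list mean of -0.78 after rescaling to equal sums, which moved the median of all genes to 0.11. A second list of platelet genes had a median change of -0.33, with 7 of 9 tested members lower, just short of the share asked for beforehand, and the exceptions were THBS1, which monocytes also express, and RAB27B. Whether platelets were fewer in blood or in the preparation cannot be told apart from these data, because no cell counts or undosed samples were analysed here.

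The higher NK list beside lower B cell and monocyte lists held in direction in both pairs on 1 run (2 of 2), which argues against the run as its whole cause. A smaller share of other cells would raise NK and T cell genes alike, and the NK list exceeded the T cell list by 0.19 ± 0.17 (SD, n = 4 pairs, from 0.00782 to 0.37), above 0.1 in 2 pairs. This leaves dilution open for the other 2 pairs, so it cannot be told apart from a change of NK cells themselves. A redistribution of blood cells after the dose was not tested and stays open, since dose and time differ together in every pair.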

How the results depend on the processing

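The count from voom, the mitochondrial list without MT-ATP8 and the estimated correlation with the run as a term were added after the data were seen. The counts of genes raised and lowered stayed at 0 under all 19 alternatives run for them. The genes past an unadjusted p of 0.05 numbered 726, and 357 with no replicate block, 1430 with no filter and 302 at a mean of at least 5 FPKM (25254 and 4574 genes tested), 1094 in the pairs on 1 run and 1549 after rescaling to equal sums. That rescaling moved the median of all genes to 0.11 and turned the split from 263 higher and 463 lower to 1342 and 207, as the mitochondrial share of the sum was lower after the dose in all 4 pairs. For the rest the cause was not tested. Leaving out each pair gave 570 to 848 genes and 10 to 17 lists. The 15 lists moved became 0 with an estimated correlation and 0 with fry.

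Estimated correlation and fry aside, 6 of the 15 list calls held in every alternative run for them: platelet (mean from -1.07 to -0.65), histone (-0.80 to -0.46), B cell (-0.42 to -0.24), NK (0.24 to 0.42), classical monocyte (-0.41 to -0.18) and MHC class II (-0.35 to -0.10). The mitochondrial list lost its call in 1, quantile normalization. List means reversed for Toll-like receptor (0.000513), immediate early (0.0409), nuclear oxidative phosphorylation (0.0631) and cytosolic ribosomal protein genes (0.0589) after rescaling to equal sums, where all 4 stayed below the median of all genes, and for glucocorticoid genes with the run as a term and in the pairs on 1 run (-0.00968 in both, which rest on the same pairs). Circadian clock genes lost their call in both as well (0.0022). Dropping the block ended the calls of the 2 T cell lists and no other. With the person as a random effect, 13 of the 15 calls were kept, 4 up and 9 down. Of 2868 values of named genes under alternatives 2802 kept their sign and 66 changed it, none past the threshold in either. The median-ratio rescaling moved nothing, since the deposited values had been scaled that way. The share of genes moving the same way in all 4 pairs was 12.98% to 14.6% in the 3 alternatives run, and the agreement between pairs had a median r of -0.077 to -0.049 in 4.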

Other observations

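The genes below and MT-ATP8 were picked after the results were seen, and the counts over splits were planned before. PRDM1, a transcription factor of plasma cells and effector lymphocytes, had 4.85 ± 2.23 FPKM before and 8.82 ± 5.03 after and was higher in all 4 pairs, while the plasma cell genes MZB1 and IRF4 were lower in all 4 (log2 changes -0.20 and -0.16). MS4A7, a marker of non-classical monocytes and macrophages, had 8.21 ± 1.16 before and 6.26 ± 1.45 after and was lower in all 4 pairs, whereas CDKN1C and RHOC of the same list went both ways. RPL30 and RPL7 had larger changes than the ribosomal list (log2 -0.45 and -0.47, against a list mean of -0.08), with SDs after the dose of 13.5 and 10.9 FPKM. Most of this lay in the pairs across runs, with -0.88 and -0.76 for RPL30 and -0.59 and -1.11 for RPL7. In the pairs on 1 run the changes were -0.07 and -0.10 for RPL30 and -0.09 and -0.10 for RPL7. None passed the adjusted test.

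The share of the FPKM sum from mitochondrial genes was 35.8%, 35.1%, 32.0% and 30.9% before and 33.3%, 28.2%, 24.2% and 23.8% after, lower after the dose in all 4 pairs. This share depends on the gene lengths used and is not a share of the reads. Of the recovered reads, mitochondrial genes held 6.44%, 6.25%, 5.5% and 5.14% before and 5.64%, 4.61%, 3.72% and 3.46% after, also lower in all 4 pairs. MT-ATP8 (mitochondrial genome, 8366 to 8572) overlaps MT-ATP6 (8527 to 9207). MT-ATP8 had 960 ± 72.8 FPKM in the 6 libraries of the main run and 14.1 times less in the mean of the 2 others, against 1.67 times for MT-ATP6, and the 2 values of the other run lay at 67.0 and 68.8.

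The count of genes past an unadjusted p of 0.05, 726, was reached by 3 of the 8 splits of the libraries that part all 4 pairs, the real one included, and the highest other count was 1859. That split sets the changes of the pairs on 1 run against those of the pairs across runs. It also sets 2 people against the 2 others, so a structure that follows the run cannot be told apart from differences between people. A split without this contrast, also parting all 4 pairs, gave 1026. With the run as a term 1004 genes had an unadjusted p under 0.05 for the day in limma, with a lowest adjusted p of 0.60. The 15 lists moved were the highest count of the 8 splits (1 of 8), and the highest other was 14. For genes past the adjusted threshold 8 of 8 splits gave at least the real count of 0, and the highest other was 0. With 8 splits no share under 0.05 can be reached. The other splits with an estimable block part only 2 pairs and compare fewer people within themselves. Each of them gave the same counts as 1 other, since the block absorbs a pair that is not parted. The 32 splits are therefore not separate comparisons, and a share of them cannot be read as a p-value. Over all 32 splits, duplicates included, 13, 1 and 32 gave as high a count.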
